A study of Rattus norvegicus with 9 samples.

How the data were processed

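RNA of the ventral spinal cord of rat embryos at embryonic day 14 was measured on 9 Affymetrix rat arrays. Per the labels, each array carried total RNA of 1 pool of 5 embryos. The labels give 4 pools with a mutant human SOD1 transgene (G93R), 4 pools with a wild-type human SOD1 transgene and 1 pool named as the negative control. The description of the negative control also says positive embryos, while its title marks it as negative; it was used here as the negative control, as both its title and the first words of its description have it. The titles of replicates 2, 3 and 4 of both transgenic groups carry the tag le2, whose meaning is not given in the sources used here. Replicate 1 of both groups and the negative control lack it. The replicate unit is the pool, so standard deviations and the p-values of single probe sets and ratios measure the spread between pools.

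The deposited table holds 1 intensity per probe set and array, on a linear scale, as the authors made it. The upstream software is not given in the sources used here. That the authors scaled the arrays was read from the values: in every array the mean after trimming the lowest and highest 2% of probe sets was 150.05, while the quantiles differed between arrays. The array medians lay between 31.0 and 33.9, and on the log2 scale they differed by at most 0.10, under the limit of 0.2 set for adding a further normalization, so none was added. All 9 array columns were used. For arrays there is no read depth; the number of arrays limits the precision.

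Of 31099 probe sets, 57 Affymetrix control probe sets were left out of the tests and used only for the 3'/5' ratios of beta-actin and GAPDH. Of the remaining 31042, the annotation table listed 20826 with 1 gene symbol and 436 with several, and 9780 had no gene. The Entrez identifiers of 20758 probe sets with 1 symbol were found in the gene table, and 0 symbols had changed. Probe sets with no symbol or several symbols stayed in the tests and were not named. Probe sequences were not matched to a genome, and no positions are given. The order of genes along chromosomes, used only to count neighbouring genes in the closing section, came from the gene table of the rat assembly GRCr8, in which 9862 tested genes with a symbol were placed.

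Intensities were taken to log2 after adding a pseudocount of 8.25, the 25th percentile of all values. Probe sets whose mean log2 value lay at or under the 40th percentile were left out, which corresponds to a mean intensity of about 17.2, and 18625 were tested. Fits used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Mutant and wild-type hSOD1 were compared on their 8 arrays alone. The mean of both transgenic groups, and each group by itself, was compared with the negative control in a fit of all 9 arrays; the single negative control is assumed there to vary like the transgenic pools. Intervals are 95% intervals of limma's moderated estimate. Single values such as 3'/5' ratios were compared by an exact two-sided permutation test.

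The groups, tests, thresholds, gene lists, naming rule and the alternatives to be tried were fixed before the data were examined. The 40 gene lists hold 758 entries on cell types, regional identity and pathways. A list was tested where at least 5 members were measured above the filter, with 1 probe set per gene (the one with the highest mean), by limma's camera with a preset correlation of 0.01; 29 lists qualified in each comparison. Its p-values with the preset correlation rest on the spread across genes and allow for little of what the genes of a list share within a pool. Camera with an estimated correlation and fry were therefore run beside it.

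Genes were named by rule. Between mutant and wild-type hSOD1, these were the 10 per direction with the largest change among probe sets past the threshold with 1 symbol and no overlap between the groups; where fewer passed, the smallest p-values in that direction filled the places and are described as not past the threshold. Against the negative control the same held with 8 per direction and all 8 transgenic values on 1 side of the negative control. From each list, up to 4 members with the smallest p were eligible, and Sod1 was always named. The other probe sets of each named gene were checked.

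The alternatives were quantile normalization, median centring, pseudocounts of 2.06 and 33.0, no filter or a filter at the 60th percentile, eBayes without trend or robust, array weights, 1 probe set per gene, the le2 tag as a covariate, leaving out the arrays without that tag, all 9 arrays in the fit, an added threshold of 1.5-fold, a replicate block, and leaving out each array in turn. The labels do not pair the pools; whether the replicate numbers pair the pools was checked by correlating, between the groups, the departures of same-numbered arrays from their group means. The log2 actin 3'/5' ratio as a covariate was added after the ratios had been seen.

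The fits were tested on simulated data made from the real means and spreads of the 18625 probe sets, with 200 changed, 50 per fold size. The folds were set on the log2 scale after the pseudocount. Near the filter they therefore stand for larger changes of intensity, and the shares recovered do not hold there for intensity folds. For mutant against wild-type hSOD1, 44% of 1.5-fold changes, 76% of 2-fold, 98% of 3-fold and 100% of 4-fold changes were recovered, with 5 false among 164 calls. For both transgenes against the negative control these shares were 16%, 62%, 80% and 90%, with 5 false among 129 calls. In each simulated comparison, 3 of 3 lists shifted by 0.3 on the log2 scale were recovered among 29 lists, and 0 others were called. The simulated genes varied independently, which real genes do not, so this count of 0 is no false-call rate for lists on real arrays.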

Results

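Gene expression in the ventral spinal cord of rat embryos at embryonic day 14 was measured on 9 Affymetrix arrays, each with total RNA of 1 pool of 5 embryos. Human SOD1 codes for a superoxide dismutase whose mutations cause a hereditary form of amyotrophic lateral sclerosis, a disease of motor neurons. The arrays fell into 4 pools with mutant hSOD1 (G93R), 4 pools with wild-type hSOD1 and 1 negative control pool, which has no replicate. Values are intensities on the authors' linear scale, given as mean ± SD, and log2 differences come from limma on intensities with a pseudocount of 8.25. The array medians lay between 31.0 and 33.9, and the correlations between arrays across probe sets lay between 0.976 and 0.986; probe sets are not independent replicates. Each transgene was represented by 1 set of labels, so mutation, rat line and site of insertion could not be told apart. The titles also carry different names, Roth for the mutant and Chan for the wild-type pools, and separate runs of sample numbers. Whatever these mark goes together with the group as well.

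The beta-actin 3'/5' ratio, a sign of RNA quality, differed between the groups. It was 7.31 ± 0.465 in the 4 mutant pools, 11.3 ± 5.29 in the 4 wild-type pools and 6.66 in the negative control, with no overlap between mutant and wild-type pools (exact two-sided permutation p = 0.0286, the smallest that 70 arrangements allow). Wild-type replicate 2 had a ratio of 19.2. Without it the groups still did not overlap, with mutant pools up to 7.98 and wild-type pools from 8.19. The exact two-sided permutation p was then 0.0571, where the smallest possible was 0.0286. The GAPDH ratio was 2.55 ± 0.0423 in mutant and 2.88 ± 0.460 in wild-type pools (exact two-sided permutation p = 0.0571). Wild-type replicate 2 also had the lowest median correlation with the other arrays, 0.978.

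**Figure D1:**
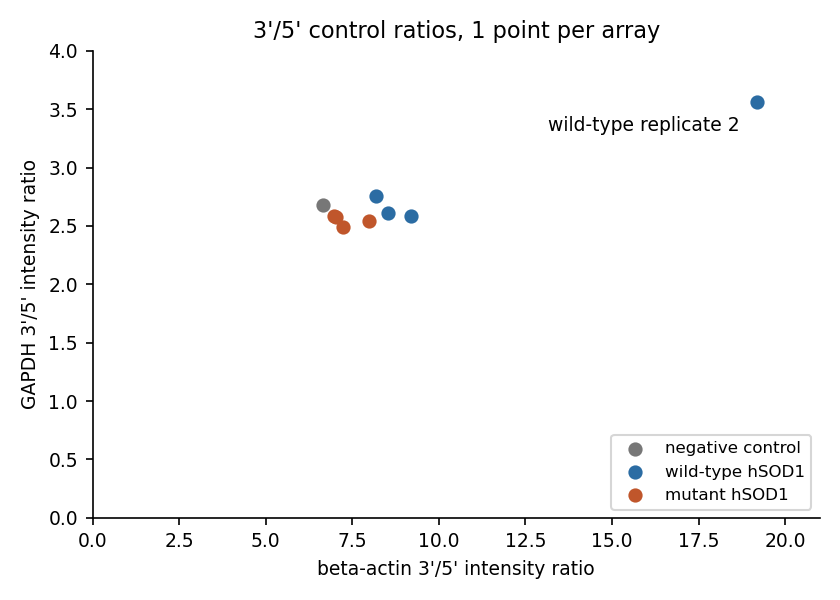
Beta-actin (horizontal axis) and GAPDH (vertical axis) 3'/5' intensity ratios on linear axes, 1 point per array, coloured by group. Wild-type replicate 2 lies apart at 19.2 and 3.56, while the actin ratios of the other 8 arrays lie between 6.66 and 9.20.

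The comparison of mutant with wild-type hSOD1 addresses how the embryonic ventral cord differs between the 2 kinds of transgene, a contrast in which the mutation goes together with the rat line and the site of insertion. Ptbp3, a polypyrimidine tract-binding protein that regulates splicing, fell to 699.9 ± 77.8 in mutant pools from 1348 ± 137 in wild-type pools (n = 4 each), a log2 difference of −0.94 (SE 0.0984, 95% interval −1.15 to −0.73, limma adjusted p = 0.0053). The negative control had 1213 for Ptbp3, near the wild-type pools. Sst, which codes for the neuropeptide somatostatin, was 183 ± 32.7 in mutant and 360.3 ± 45.4 in wild-type pools, a log2 difference of −0.95 (SE 0.131, limma adjusted p = 0.0371), and 158 in the negative control. Ddx42, a DEAD-box RNA helicase, was 22.5 ± 1.57 in mutant and 74.97 ± 22.2 in wild-type pools on 1 probe set, a log2 difference of −1.40 (SE 0.184, limma adjusted p = 0.0337), and 21.5 in the negative control. These 3 probe sets (1382005_at, 1367762_at and 1379896_at) were all that passed of 18625, with 0 higher and 3 lower in mutant pools.

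Other probe sets of the same genes gave a mixed picture. The second Ddx42 probe set, 1376596_at, was 568 ± 61.8 in mutant and 525 ± 47.7 in wild-type pools, a log2 difference of 0.11 with a 95% interval from −0.11 to 0.33. The second Ptbp3 probe set, 1387432_at, lay below the filter at 6.20 ± 2.68 and 12.9 ± 4.90. At an unadjusted p under 0.05 stood 923 probe sets, 4.96% of those tested, with 515 higher and 408 lower in mutant pools. The groups did not overlap at 551 probe sets, 2.96%, where chance gives 2.86%. Ptbp3 stayed past the threshold when any 1 of the 8 arrays was left out, while Sst kept its call only without mutant replicate 2 or wild-type replicate 2 and Ddx42 only without wild-type replicate 4. Without wild-type replicate 2, Ptbp3 and Sst made 2 calls. With the actin ratio as a covariate, without an intensity trend, or without the arrays that lack the le2 tag, 0 probe sets passed in limma, with 681, 996 and 682 at an unadjusted p under 0.05. Without a filter or with the tag as a covariate, only Ptbp3 did.

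Rat Sod1 itself (1367641_at) was 2279 ± 247 in mutant, 2245 ± 157 in wild-type pools and 1699 in the negative control. Its log2 difference between mutant and wild-type pools was 0.02, with a 95% interval from −0.16 to 0.20 (limma adjusted p = 0.982), and its sign changed with the setting. The level in every one of the 8 transgenic arrays lay above that of the negative control, by 0.41 on average on the log2 scale (SE 0.126, limma adjusted p = 1.00). Whether this probe set picks up the human transcript could not be determined here.

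**Figure D2:**
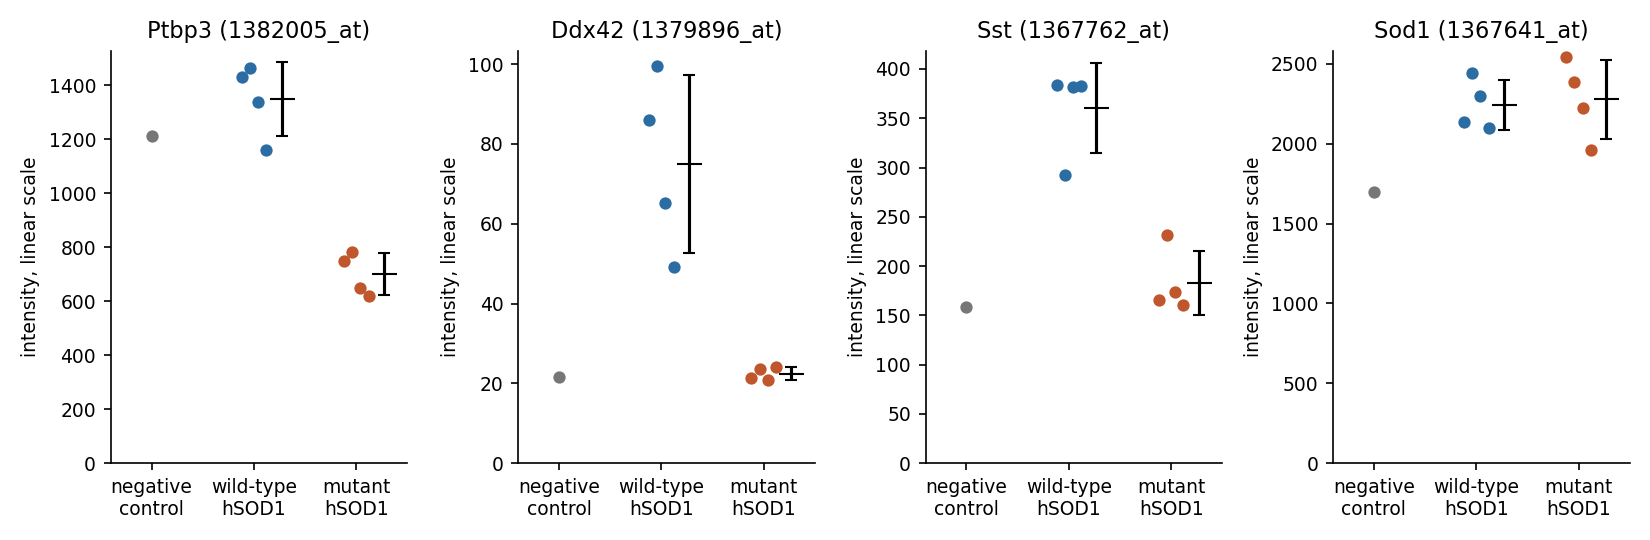
Intensity (linear vertical axis from 0) of Ptbp3, Ddx42, Sst and Sod1 in the negative control, wild-type and mutant hSOD1 pools; points are arrays, and the bar beside each group of 4 gives its mean ± SD. For Ptbp3 the mutant pools (699.9 ± 77.8) stand apart from the negative control at 1213, and for Sst and Ddx42 the wild-type pools (360.3 ± 45.4 and 74.97 ± 22.2) do so from 158 and 21.5.

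The next genes by p-value did not pass. On the lower side, Sc5d, an enzyme of cholesterol synthesis, was 83.1 ± 14.3 in mutant and 164 ± 20.9 in wild-type pools (limma adjusted p = 0.0599), while its other probe sets differed by −0.45 and 0.11 on the log2 scale. Sema6a, a semaphorin of axon guidance, was 178 ± 39.97 against 345 ± 61.9 (limma adjusted p = 0.133), and Gpr161, a receptor of the primary cilium that restrains hedgehog signalling, was 614 ± 81.3 against 1002 ± 155 (limma adjusted p = 0.162). Ubl5, a ubiquitin-like protein, was 271 ± 26.1 against 398 ± 22.9, and Setd1b, Mga and Dennd1b differed by −0.79, −0.86 and −0.93 on the log2 scale. Other probe sets above the filter differed by less: Sema6a by −0.16, Gpr161 by 0.01, Ubl5 by −0.14, Mga by −0.11 and Dennd1b by −0.07 and −0.09. In the negative control the named probe sets of Ubl5, Setd1b, Mga and Dennd1b stood at 226, 117, 44.3 and 74.2, and those of Sc5d, Sema6a and Gpr161 at 109.7, 172 and 649. On the higher side, of which 1 gene is not described here, Serpine2, Pkd2, Msmp, Rab3d and Dnase1 were higher by 0.47, 0.75, 0.86, 0.52 and 0.61, and Albfm1, N4bp2l1, the growth factor gene Ptn and the homeobox gene Hoxa5 by 0.85, 0.68, 0.36 and 0.28 on the log2 scale (limma adjusted p of 0.668 to 0.698). The other Pkd2 probe set differed by −0.04. Across the alternatives the differences of Pkd2, Dnase1, Albfm1 and N4bp2l1 fell as low as 0.40, 0.35, 0.50 and 0.37. They rose as high as 0.97, 0.75, 1.06 and 0.86, so their size depends on the setting. Ptn was 506 ± 36.7 in mutant, 392 ± 29.9 in wild-type pools and 522 in the negative control.

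None of the 29 gene lists passed between mutant and wild-type hSOD1 (0 by limma's camera and 0 by fry), and 5 had an unadjusted p under 0.05. Of the 17 measured motor neuron genes, 13 were higher in mutant pools, with a mean difference of 0.13 on the log2 scale (camera adjusted p = 0.104, and 0.990 as adjusted p with an estimated correlation). Isl1, a transcription factor of motor neurons, was 468 ± 104 against 337 ± 36.9, and Aldh1a2, which makes retinoic acid, was 1695 ± 644 against 1104 ± 234. Of 7 ventral interneuron genes, 6 were lower, with a mean of −0.17 (camera adjusted p = 0.104; adjusted p = 0.925 with an estimated correlation). Gata3 was 135 ± 29.1 against 183 ± 37.9 and Gata2 105 ± 13.8 against 130.5 ± 45.6. Glutamate receptor genes were lower at 10 of 13, with a mean of −0.11 (camera adjusted p = 0.104; adjusted p = 0.925 with an estimated correlation). Grin2b was 24.2 ± 2.99 against 34.3 ± 8.14. Genes of p53 and apoptosis were higher at 10 of 11, with a mean of 0.14 (camera adjusted p = 0.142; adjusted p = 0.925 with an estimated correlation). Bbc3 was 143 ± 19.7 against 106 ± 15.8 and Mdm2 369 ± 35.5 against 320.4 ± 14.6. Cervical and brachial Hox genes were higher at 8 of 10, with a mean of 0.11 (camera adjusted p = 0.175; adjusted p = 0.925 with an estimated correlation). Hoxa5 was 2266 ± 143 against 1866 ± 113, while Hoxd3 was 421 ± 54.6 against 517 ± 86.5. The actin ratio differed between the same groups, and with it as a covariate the Hox list alone passed (camera adjusted p = 0.00107). Leaving out mutant replicate 2, mutant replicate 4 or wild-type replicate 1 gave 2 lists past the threshold each, and leaving out wild-type replicate 2 gave 1, the Hox list. These list calls, with the covariate or without an array, came from camera with the preset correlation alone. With it, 29 of the 34 other splits of the 8 arrays into 4 and 4 also gave 1 or more lists. The motor neuron mean was 0.04 without mutant replicate 1 and 0.20 without mutant replicate 4. Without wild-type replicate 2 the means of the ventral interneuron, glutamate receptor and p53 lists were −0.08, −0.06 and 0.07, and with the actin ratio as a covariate they were 0.0059, −0.03 and 0.03, so that the sign of the ventral interneuron list turned.

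The other 24 lists had camera adjusted p from 0.374 to 0.987. Synaptic vesicle genes were lower at 12 of 17, with Sv2b at 497 ± 31.9 against 690.0 ± 103. Of 8 sensory ganglion genes 5 were higher, with Runx1 at 111 ± 15.1 against 70.7 ± 24.2 and Sncg at 3476 ± 681 against 2719 ± 141. Neural progenitor genes were higher at 7 of 13, with Slc1a3 at 83.4 ± 5.21 against 111 ± 10.2 and Dll1 at 60.1 ± 2.35 against 48.1 ± 3.63, astrocyte genes at 2 of 7, cartilage genes at 1 of 5 and cell cycle genes at 8 of 15. Among stress pathways, higher members numbered 14 of 21 for the unfolded protein response, with Xbp1 at 895 ± 73.6 against 763 ± 119, 6 of 14 for oxidative stress, 6 of 10 for heat shock, 2 of 9 for metallothioneins and metal handling, 10 of 24 for the proteasome and 9 of 18 for autophagy and lysosomes. In metabolism they numbered 14 of 36 for oxidative phosphorylation, 12 of 20 for glycolysis and hypoxia, 10 of 15 for cholesterol synthesis and 8 of 19 for ribosomal proteins. In neuronal function they numbered 12 of 20 for axonal transport, 10 of 21 for axon guidance, 7 of 13 for GABA and glycine, 6 of 11 for ion channels, 6 of 12 for neurotrophic signalling and 4 of 7 for immediate early genes. Genes linked to amyotrophic lateral sclerosis were higher at 9 of 14, with Vapb at 576 ± 72.3 against 507.5 ± 43.6, and thoracic and lumbosacral Hox genes at 4 of 8, with Hoxa10 at 692 ± 68.8 against 864 ± 105. Adjusted over the list alone, 4 members passed (Runx1, Sncg, Sv2b and Hoxa5), against 0 list members over all genes in limma. The mean, median and test differed in sign for 6 lists.

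**Figure D3:**
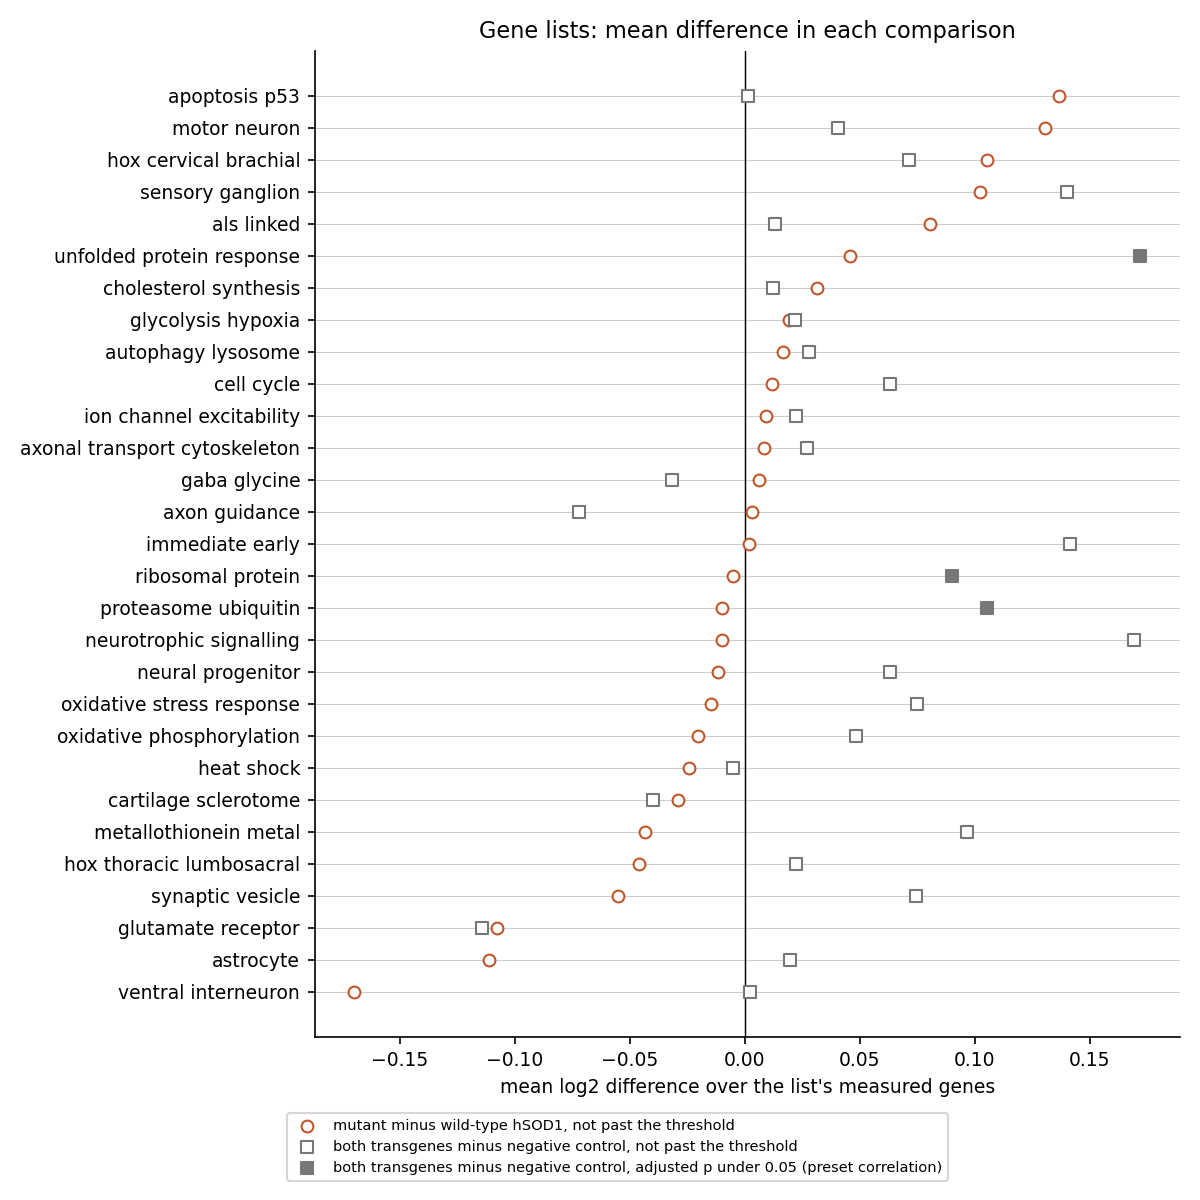
Mean log2 difference (horizontal axis) over the measured genes of each of 29 gene lists (vertical axis), for mutant minus wild-type hSOD1 (circles) and both transgenes minus the negative control (squares); filled symbols have a camera adjusted p under 0.05 with the preset correlation. None of the circles is filled, and 3 squares are, for the unfolded protein response at 0.17, the proteasome at 0.11 and ribosomal proteins at 0.09.

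The comparison of both transgenes with the negative control addresses what changes with a human SOD1 transgene of either kind, with 1 control pool. The title of the control carries SDneg in place of Roth or Chan. The transgene therefore goes together here with whatever these names mark. Proteasome genes, which code for the protease that degrades ubiquitin-tagged proteins, were higher with a transgene at 20 of 24 members, with a mean of 0.11 on the log2 scale (camera adjusted p = 0.00414; adjusted p = 0.973 with an estimated correlation). Psmd4 was 609.9 ± 41.3 in the 8 transgenic pools and 447 in the negative control, and Psma7 1837 ± 117 and 1489. Genes of the unfolded protein response were higher at 13 of 21, with a mean of 0.17 (camera adjusted p = 0.0213; adjusted p = 0.792 with an estimated correlation). Among them the transcription factor gene Atf4 was 1500.2 ± 142 against 1054, Herpud1 457 ± 122 against 221, Trib3 21.6 ± 4.79 against 8.63 and the chaperone gene Hspa5 3017 ± 222 against 2549. Of the 8 members lower with a transgene, the transcription factor gene Xbp1 was 829 ± 116 against 991 and the chaperone gene Canx 2407 ± 182 against 2598, and the median difference of the list was 0.12. Ribosomal protein genes were higher at 15 of 19, with a mean of 0.09 (camera adjusted p = 0.0176; adjusted p = 0.973 with an estimated correlation). Rps9 was 2361 ± 174 against 1929.9 and Rpl35 3624 ± 199 against 3190.5.

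These 3 were all that passed of 29 lists, each with the preset correlation alone: with an estimated correlation 0 passed (1 at an unadjusted p under 0.05), and by fry 1 did, neurotrophic signalling (fry adjusted p = 0.0174; camera adjusted p = 0.111). Its members were higher at 10 of 12, with a mean of 0.17; the neurotrophin gene Bdnf was 26.6 ± 4.48 against 15.4 and Igf1 72.9 ± 17.0 against 46.3. Adjusted over the list alone, 2 members passed (Atf4 and Herpud1), against 0 list members over all genes in limma. The other lists had camera adjusted p from 0.111 to 0.998, and mean, median and test differed in sign for 8. The ribosomal list lost its call without mutant replicate 1 (mean 0.07, camera adjusted p = 0.0646), without a filter (0.06, adjusted p = 0.0730) and with the actin ratio as a covariate (0.07, adjusted p = 0.154). The unfolded protein response list lost its call with the le2 tag as a covariate, at an unchanged mean of 0.17 (adjusted p = 0.0520). When each of the 8 transgenic arrays was set alone against the other transgenic arrays, 3 of them gave 3 or more lists with the preset correlation.

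No single probe set passed against the negative control: limma called 0 of 18625 for both transgenes together, for mutant and for wild-type hSOD1, with 581, 427 and 797 at an unadjusted p under 0.05. Atxn2l, a relative of the RNA-binding protein ataxin-2, came nearest, at 35.8 ± 7.92 in the 8 transgenic pools and 2.21 in the negative control (log2 difference 2.05, SE 0.276, limma adjusted p = 0.0839). Its log2 difference was 3.12 with a pseudocount of 2.06 and 0.96 with 33.0, and it passed under 4 of 18 alternatives, among them leaving out wild-type replicate 1. The signalling adaptor gene Traf6 was 54.7 ± 16.1 against 13.1, but its other probe sets differed by −0.16, 0.30 and 0.10 on the log2 scale. Zfp346 was 130.1 ± 16.4 against 64.0, Thy1, a surface glycoprotein of neurons, 24.7 ± 6.80 against 3.74, and LOC100911177 535 ± 58.6 against 347. Zbtb7a was 23.7 ± 4.85 against 5.48, Tars2 21.1 ± 5.30 against 4.06 and Fbxo10 25.7 ± 5.71 against 5.89. The other probe sets above the filter of Zfp346 and Tars2 differed by −0.02 and 0.06, and another of Thy1, below the filter, by −0.13. Since Atxn2l, Thy1, Zbtb7a, Tars2 and Fbxo10 lay below the pseudocount in the negative control, the size of their log2 differences is set by it. Lower with a transgene were Alkbh1, a demethylase of nucleic acids, at 322 ± 42.6 against 486, Ccm2 at 155 ± 14.3 against 251 and the transcription factor gene Zeb2 at 22.9 ± 2.88 against 47.5. The other Zeb2 probe sets differed by −0.09, −0.23, 0.43 and 0.11. Dnmbp, Mettl13, Ints7, Ptprd and Nol9 differed by −0.67, −0.62, −0.48, −0.61 and −0.36, and other probe sets above the filter by −0.36 for Ints7 and by −0.12 and −0.23 for Ptprd. For each gene all 8 transgenic values lay on 1 side of the single negative control. The naming rule asks this only of probe sets past the threshold, but choosing by the smallest p favours it.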

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

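The tests of the actin ratio as a covariate, of the gene lists in other splits, of each transgenic array set alone, and of both explanations for wild-type replicate 2 were chosen only after the results were seen. Of 82 sets of 4 values looked at (Dixon's test within a group), 4 had a value far from the other 3; chance gives about 1 in 20. In wild-type replicate 2 the beta-actin 3'/5' ratio was 19.2 (others 8.19 to 9.20). The Sst intensity in the same array was 292 (others 382 to 384), on the side of the mutant pools. The Rab3d intensity in wild-type replicate 3 was 91.8 (others 67.3 to 71.0). The Dnase1 intensity in wild-type replicate 4 was 26.0 (others 18.0 to 18.3).

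Ptbp3, Sst and Ddx42 were the 3 probe sets lower in mutant than in wild-type pools. Of the 35 splits of the 8 arrays into 4 and 4, 2 gave as many probe sets, the real one with 3 and that of replicates 1 and 3 against replicates 2 and 4 of both groups with 4, so chance could not be excluded; for gene lists this count says nothing, since all 35 splits must give at least the real 0 (the highest other gave 10). For Ddx42 the other probe set, with a log2 difference of 0.11 and an interval that excludes −1.40, is consistent with an effect on this probe set alone, such as a transcript form or a sequence variant under the probes, and not on all Ddx42 RNA. With the actin ratio in the fit the median difference of the 3 was −1.09: Ptbp3 went from −0.94 (SE 0.0984) to −0.84 (SE 0.113), Sst from −0.95 (SE 0.131) to −1.09 (SE 0.150) and Ddx42 from −1.40 (SE 0.184) to −1.12 (SE 0.189), all 3 intervals stayed below 0, and the calls ended (adjusted p of 0.0983, 0.0983 and 0.312) with the smaller differences of 2 genes and larger errors, so the ratio as a part of the cause stays open. An effect of the mutation, of the rat line and of the insertion site cannot be told apart in this design, where each transgene has 1 set of labels.

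The proteasome, unfolded protein response and ribosomal lists were higher in transgenic pools than in the negative control, which is a single array. When each of the 8 transgenic arrays was set alone against the others, the largest mean shift of the proteasome list was 0.110 (mutant replicate 4), against 0.105 for the negative control, and that of the ribosomal list 0.158 (mutant replicate 4), against 0.0900, so the departure of any one array may account for both. For the unfolded protein response the largest was 0.0946 (wild-type replicate 2), against 0.172, which is larger but not by the margin of 2 that was set. With 1 control, a departure of the negative control pool alone and an effect of the transgenes cannot be told apart. Nor can whatever the different names in the titles mark. Set alone, 3 of the 8 transgenic arrays gave 3 or more lists, with a range from 0 to 8, and in fits of another form, the 34 other splits into 4 and 4, 29 gave 1 or more lists and 21 gave 3 or more. The negative control lacks the le2 tag, as do 2 transgenic arrays. In these 2 the mean differences from it were 0.17, 0.14 and 0.13 for the unfolded protein response, proteasome and ribosomal lists. The fit with the tag as a covariate gives the same means, so they are not separate evidence, and in it the unfolded protein response list lost its call. Mutant replicate 1, 1 of these 2 arrays, itself lay high for 2 of the lists. The mean shift of the other transgenic arrays from it was −0.0766 for the proteasome and −0.119 for the ribosomal list. For these 2 lists the means therefore cannot decide about the tag. For the unfolded protein response that shift was −0.0100. There the mean of 0.17 argues against the tag as the whole cause, though from 1 array per group.

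Wild-type replicate 2 stood apart from the other arrays: set alone, it gave 299 probe sets past the threshold, where the other transgenic arrays gave 0 or 1. Its actin 3'/5' ratio was 2.08 times the highest of the other 8 arrays, and its GAPDH ratio of 3.56 lay above their range of 2.49 to 2.76, which is consistent with a stronger 3' bias of the RNA on this array. For RNA of other cell types, 83 marker genes of microglia, muscle, cartilage, meninges, endothelium and blood had a median log2 difference of 0.0628 from the other 3 wild-type arrays (bootstrap interval −0.0122 to 0.1995). This median does not reach the 0.5 set for this cause and lies below the 0.1 set against it. The interval, which was not part of these bounds, includes values above 0.1. With 1 array it does not measure the spread between pools. Most of the marker genes lay below the filter (13 of 14 for microglia, 12 of 16 for muscle), where the pseudocount shrinks log2 differences. The test could therefore miss a small share of such RNA. No biological explanation was tested, since the labels name no difference between this pool and the others of its group.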

How the results depend on the processing

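The actin 3'/5' ratio as a covariate was the only alternative chosen after seeing the data. The causes of the changes given here were not tested, except that leaving out arrays also leaves fewer samples. For mutant against wild-type hSOD1 the count of 3 probe sets became 5 with median centring (Sc5d and Sema6a added), 1 without a filter and with the le2 tag as a covariate (Ptbp3), and 0 without trend, without the arrays lacking the tag, and with the actin ratio; other settings gave 2 or 3. Leaving out 1 array gave 1 to 3, with 1 without mutant replicate 1, wild-type replicate 1 or wild-type replicate 3. Ptbp3 had an adjusted p of 0.0999 without trend, 0.113 without the arrays lacking the tag and 0.0983 with the actin ratio, in a range from 0.00109 to 0.113. The Sod1 difference of 0.02 became −0.0026 with median centring and −0.0588 without the arrays lacking the tag, and lay between −0.0366 and 0.0870 when 1 array was left out (below 0 without mutant replicate 1, mutant replicate 2, wild-type replicate 1 or wild-type replicate 4), with adjusted p from 0.933 to 1.00. The count of 0 gene lists became 1 with the actin ratio (cervical and brachial Hox genes) and 0 to 2 when 1 array was left out: 2 without mutant replicate 2 (motor neuron, ventral interneuron), mutant replicate 4 (motor neuron, glutamate receptor) or wild-type replicate 1 (ventral interneuron, p53 and apoptosis), and 1 without wild-type replicate 2 (the Hox list). The mean of the ventral interneuron list turned to 0.0059 with the actin ratio.

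Against the negative control, the count of 0 probe sets for both transgenes became 1 (Atxn2l) with median centring, a pseudocount of 2.06 and 1 probe set per gene, and lay between 0 and 1 when 1 array was left out (1 without wild-type replicate 1). The same 3 settings and the same array gave 1 for wild-type hSOD1 (range 0 to 1), and the pseudocount of 2.06 gave 1 for mutant hSOD1 (0 in every case when 1 array was left out). The 3 lists became 0 with an estimated correlation and 1 with fry, and 2 to 4 when 1 array was left out (2 without mutant replicate 1, and 4 without mutant replicate 4, with oxidative phosphorylation added); 2 passed with the tag as a covariate, 2 with the actin ratio (the ribosomal list had an adjusted p of 0.154) and 2 without a filter (0.0730).

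With a replicate block, 3 probe sets passed (Ptbp3, Ddx42 and Tm9sf3; Sst had an adjusted p of 0.0860) and 0 lists did. Departures of same-numbered arrays correlated between −0.0761 and 0.201 across probe sets, with 2 of 4 pairs over 0.1. Pairs of different numbers reached −0.227 and 0.209. These values show no clear pairing by replicate number and cannot exclude it. Of 67 alternatives for the 3 called probe sets (Ptbp3, Sst and Ddx42), 28 ended the call and 39 kept it. Apart from Sod1 between mutant and wild-type pools, given above, the other named genes were not past the threshold to begin with; 9 of their 690 alternatives brought a call, and 0 reversed the direction. The scalings moved the median of all probe sets from 0.0134 to −0.00677 at most for mutant against wild-type hSOD1. Low signal limits what can be read near the filter at an intensity of about 17.2, where Ddx42, Pkd2 and Dnase1, among others, lie in 1 of the groups.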

Other observations

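The test of uneven distances from the negative control and the looks at Xist and at the globin genes of mutant replicate 3 were chosen only after results were seen. The 11 gene lists with fewer than 5 members above the filter are given as medians of the group means in mutant, wild-type and negative control pools. Blood genes lay at 3.85, 3.21 and 2.48, but 3 globin genes stood apart in mutant replicate 3. Hbe1 was 94.5 there and at most 11.6 in the other 8 arrays, Hbg1 40.5 and at most 2.18, and Hbz 15.5 and at most 0.863, while Hbb was 3.52. Endothelial genes lay at 8.22, 7.47 and 7.43, microglial genes at 10.3, 7.79 and 8.59 (no group mean above 22.0), and genes of meninges and fibroblasts at 8.11, 8.24 and 9.48. Skeletal muscle genes lay at 10.2, 10.2 and 8.57, with Acta1 at 96.9 ± 15.4 in mutant and 85.2 ± 18.4 in wild-type pools, and genes of neural crest and Schwann cells at 17.1, 18.8 and 16.5. Interferon and immune genes lay at 8.37, 9.03 and 6.63, and genes of the oligodendrocyte lineage at 12.1, 12.4 and 15.7. Dorsal spinal cord genes lay at 10.2, 13.0 and 20.5 and floor plate genes, which mark the ventral midline, at 38.5, 48.4 and 27.8; among the latter the secreted guidance factor Slit2 was 470.2 ± 72.9 in mutant and 486 ± 112 in wild-type pools, and Spon1 319 ± 15.2 and 339 ± 50.3.

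The pools differed in sex-linked transcripts. Xist, expressed from the inactive X chromosome, was 1710.3, 1885, 1356 and 2674 in mutant replicates 1 to 4, 2155, 2688, 1947 and 1442 in wild-type replicates 1 to 4, and 3064 in the negative control. The Y-linked Eif2s3y was 260.2, 544, 556 and 199 in the mutant and 727, 367, 585 and 527 in the wild-type replicates, and 294 in the negative control. The Y-linked list as a whole had medians of 173, 165 and 181 over 3 genes, which were the values of Uty. Sry lay at 4.69, 2.93 and 3.75, below the pseudocount. Between mutant and wild-type pools Eif2s3y differed by −0.58 on the log2 scale (SE 0.310), at 390 ± 187 against 551 ± 149. Xist differed by −0.12 (SE 0.207) and Uty by 0.07 (SE 0.111). The labels do not give the sexes of the embryos, and a part of sex in the group differences was not tested.

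If the 2 rat lines differed in stretches of the genome near the insertion or from their breeding, neighbouring genes should differ together. Among the 100 genes with a symbol and a place in the gene order that had the smallest p between mutant and wild-type pools, 8 pairs lay within 10 gene positions of each other, where 10000 random sets of 100 genes had a median of 10, an SD of 3.14 and a 95th percentile of 15. The bound set beforehand against this explanation was a count at or below the random median, which 8 meets. It does so by less than 1 SD of the random sets, a margin set after the count was seen, so this explanation stays open. A second hypothesis was that the wild-type line departs from the negative control more than the mutant line does. At 67 of the 100 genes with a symbol and the smallest p, chosen anew in each split, the negative control lay nearer the mutant mean, but 7 of 35 splits were as uneven and the highest other split had 80, and the count ranged from 53 without mutant replicate 4 to 84 without wild-type replicate 4, so these data may reflect single arrays as well as the line.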
